A study of Homo sapiens with 6 samples.

How the data were processed

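RNA was extracted with TRIzol from HaCaT cells, an immortalised human keratinocyte line, and sequenced from Illumina libraries, per the labels' protocols. There were 6 libraries. The 3 titled CD274_OE are labelled as overexpressing PD-L1, the protein encoded by CD274. The 3 titled NC are labelled as normal HaCaT cells. One label describes the overexpression as mediated by an shRNA, a reagent that lowers its target, so the level of CD274 in each library was used to check the titles. The labels do not say that the replicates came from separate cultures, and p-values therefore measure the spread between these libraries, which may be technical.

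The authors deposited one table of whole-number counts per gene, with Ensembl gene identifiers. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9, although the identifiers are those of human genes. The human build, the annotation, the counting program and the use of strand are not given in the sources used here. The counts were used as deposited. The table lists 50868 genes, of which 28361 had at least 1 count and 49659 matched a symbol in the table of gene names used. Coordinates are those of GENCODE 29 on GRCh38, 1-based, and are given for orientation, since they may differ from the annotation behind the counts. Transcript length and GC content came from the longest transcript of each gene in that release.

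Depth ranged from 15813780 to 20748307 counts per library, and 21384 to 22725 genes were detected. Levels are given as CPM, the counts of a gene scaled to library size by the cpm function of edgeR. No pair of libraries within a group agreed within sampling noise: chi-square per gene was 13.3 to 24.0 over the 6 pairs, in genes with at least 20 counts in the pair.

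Genes with low counts were removed with filterByExpr in edgeR 4.0.16 under R 4.3.3, which left 14467 genes. Libraries were scaled with TMM factors, which lay between 0.98 and 1.01. CD274_OE was compared with NC by edgeR's quasi-likelihood test (estimateDisp, glmQLFit with robust estimation, glmQLFTest) with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Fold changes are log2 values of CD274_OE over NC with standard errors, levels use TMM-scaled library sizes and are given as mean ± SD, and tests are two-sided. Exact permutation tests of log2 CPM were added for single genes, and 3 libraries against 3 cannot give a p below 0.1.

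The 27 gene lists were fixed before the data were examined. Each was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. The test was repeated with an estimated correlation and with fry, which asks whether the members of a list move one way on balance and does not compare them with other genes. A mixed form of fry, which asks whether members change in either direction, was run in the main fit alone. Members past the threshold were counted over all genes and adjusted over the list alone.

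The rule for named genes was fixed at the same time. It takes CD274, IRS4 and EIF3I whatever their result, then the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean of at least 1 CPM groups that do not overlap and a symbol that is not a clone, LOC, pseudogene or antisense name, or all of them where fewer pass (the 5 smallest p in each direction where none passes). In each list it takes up to 4 members past the threshold over all genes or, where none passes, up to 2 with the highest mean CPM, and a member that goes against the rest may be named. Genes named outside this rule are said to have been chosen after their values were seen.

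The analysis was tested on simulated counts for the 14467 genes of the comparison of CD274_OE with NC. Of 50 genes changed at each fold size, 46% were recovered at 1.5-fold, 86% at 2-fold, 98% at 4-fold and 98% at 8-fold, with 12 false calls. With no change simulated, 2 genes were called and 652 had an unadjusted p under 0.05. A list shifted by -0.3 on the log2 scale was called, and 0 other lists were. Each gene was drawn independently, so members of a list were not correlated and the libraries had no structure besides the groups. The simulation therefore cannot show how the list tests and recovery rates hold where such correlation or structure is present.

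The comparison was repeated with RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library in turn. After the data were seen, 2 fits were added: offsets that remove trends with GC content and transcript length in each library (natural splines with 5 degrees of freedom each), and a fit without NC replicates 1 and 2. A plasma cell list, a B-lineage list, a list of further endoplasmic reticulum genes and a division of the stress list into parts were also added after the data were seen. Python 3.11.15 with SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.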

Results

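Gene counts from 6 HaCaT libraries were compared, 3 from cells overexpressing PD-L1 (CD274_OE) and 3 from normal cells (NC). HaCaT is a spontaneously immortalised line of human epidermal keratinocytes. The libraries held 20573668, 20748307 and 15813780 counts in CD274_OE replicates 1 to 3 and 19231654, 18482792 and 19410406 in NC replicates 1 to 3. The series title links PD-L1 to eIF3I, a subunit of the translation initiation factor eIF3, to the insulin receptor substrate IRS4 and to wound healing in diabetes, and the comparison addresses which transcripts differ when PD-L1 is raised in keratinocytes.

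CD274 was 25.3-fold higher in the CD274_OE libraries. CD274 (ENSG00000120217) encodes PD-L1, the ligand of the T cell receptor PD-1, and lies on chromosome 9, positions 5450503 to 5470566, plus strand. Its counts were 3137, 2439 and 2144 in CD274_OE and 100, 102 and 108 in NC, so all 6 libraries matched their titles. The mean level was 137 ± 18.4 CPM (SD, n = 3) against 5.39 ± 0.216 CPM (SD, n = 3). The log2 fold change was 4.66 (SE 0.126), with an edgeR quasi-likelihood adjusted p of 5.37e-06.

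HSPA5 was the other gene past the threshold, and it was 35.2% lower in CD274_OE. HSPA5 (ENSG00000044574) encodes BiP, the main Hsp70 chaperone of the endoplasmic reticulum, and lies on chromosome 9, positions 125234853 to 125241330, minus strand. Its level was 2073 ± 34.6 CPM (SD, n = 3) in CD274_OE and 3199 ± 30.0 CPM (SD, n = 3) in NC. The log2 fold change was -0.63 (SE 0.0579), with an edgeR adjusted p of 0.037. The call was lost without CD274_OE replicate 1 (adjusted p = 0.079), CD274_OE replicate 2 (0.162), NC replicate 1 (0.174), NC replicate 2 (0.157) or NC replicate 3 (0.12), and kept without CD274_OE replicate 3 (0.0312), with log2 fold changes between -0.63 and -0.61. Over all other settings and tools run, the adjusted p of HSPA5 ranged from 1.25e-15 with DESeq2 to 0.848 with the replicate number as a block.

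Of the 14467 genes tested, 2 passed the threshold, 1 higher and 1 lower in CD274_OE. The simulation with no change also called 2 genes, so the count alone does not set the real comparison apart. At an unadjusted p under 0.05 there were 1108 genes, 422 higher and 686 lower, against 723 expected with no difference. This unadjusted count was 526 without NC replicate 1, 591 without CD274_OE replicate 2, 631 without NC replicate 2, 819 without CD274_OE replicate 1, 1738 without NC replicate 3, 2377 without CD274_OE replicate 3 and 614 with the replicate number as a block, so the excess is not a stable property of the comparison. The groups did not overlap in 1951 genes (13.5%), where chance gives 10%. DESeq2 called 22 genes, 5 higher and 17 lower. With edgeR, 4 genes passed without CD274_OE replicate 1, 4 without CD274_OE replicate 2 and 5 without CD274_OE replicate 3. Leaving out NC replicate 1, 2 or 3 gave 3 genes each. Only CD274 passed in more than 1 of these fits, so the larger counts are not a growing set of the same genes. Among the calls without NC replicate 3 was MZB1 of the plasma cell list (adjusted p = 0.0305).

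IRS4 was low in all libraries and lower still in CD274_OE. IRS4 (ENSG00000133124), which encodes an adaptor of the insulin and IGF1 receptors, lies on chromosome X, positions 108732482 to 108736409, minus strand. It had 3, 5 and 1 counts in CD274_OE and 57, 27 and 26 in NC. Pooled over libraries, 9 counts against 110 gave a ratio of 0.0818, with an exact 95% interval of 0.0364 to 0.161 that covers counting error only. The level was 0.152 ± 0.0908 CPM (SD, n = 3) against 1.91 ± 0.893 CPM (SD, n = 3). The log2 fold change of -3.54 (SE 0.519) had an edgeR adjusted p of 0.229 over all genes and did not pass; it was 0.00498 adjusted over the list alone, in the insulin and IGF list. IRS4 passed with DESeq2 (adjusted p = 1.44e-04) and with no filter on low counts (edgeR adjusted p = 0.00311), and its adjusted p ranged from 1.44e-04 to 0.848 over the settings and tools run. The next gene downstream on the same strand, ENSG00000261409 at positions 108719949 to 108724944, was chosen after its values were seen: it had 5, 1 and 2 counts in CD274_OE and 59, 34 and 33 in NC. Its log2 fold change was -3.89 (SE 0.477), with an edgeR adjusted p of 0.116. In these coordinates the 2 genes share a strand and do not overlap, so strand has no bearing on telling them apart. Without strand information, their counts cannot be fully separated from those of the antisense gene IRS4-AS1, which had at most 3 counts in any library.

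EIF3I did not differ detectably between the groups. EIF3I (ENSG00000084623) lies on chromosome 1, positions 32221928 to 32231604, plus strand, and was at 358 ± 39.6 CPM (SD, n = 3) in CD274_OE and 329 ± 28.0 CPM (SD, n = 3) in NC. The log2 fold change was 0.12, with a 95% interval of -0.11 to 0.35 and an edgeR adjusted p of 0.71. It was 0.032 without CD274_OE replicate 1 and 0.20 without NC replicate 3, the ends of the range with 1 library left out. Two-sided exact permutation tests gave p = 0.4 for EIF3I and p = 0.1, the smallest possible, for CD274, HSPA5 and IRS4.

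**Figure D1:**
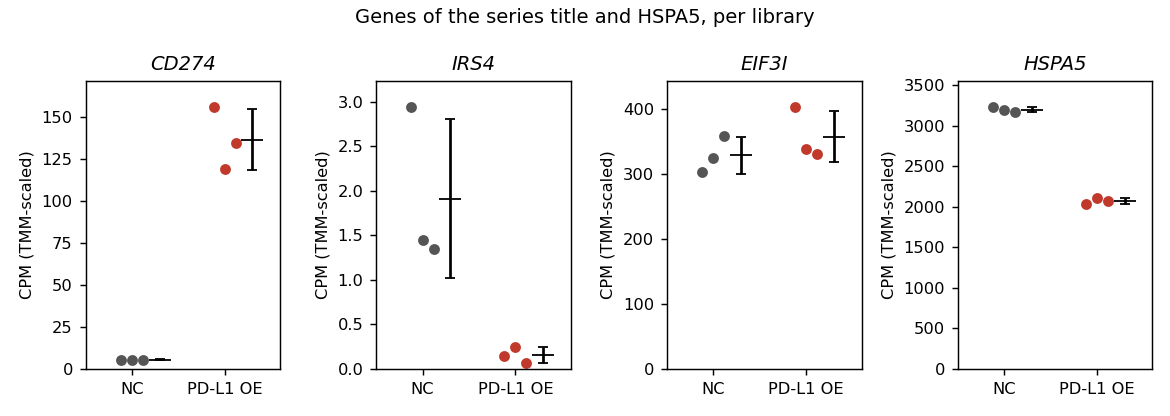
Level of CD274, IRS4, EIF3I and HSPA5 in TMM-scaled CPM, with 1 point per library (grey, NC; red, PD-L1 overexpression) and the mean and SD of each group in black. The groups do not overlap for CD274, IRS4 and HSPA5 and overlap for EIF3I.

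Of the 27 fixed lists, camera called 5 with its preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.186). For 1 direction, fry called 2, the unfolded protein and integrated stress response list and the checkpoint ligand list. The checkpoint list holds CD274, the overexpressed gene, and fry was not run without it, so that call is no sign of a response of the other members. With the preset correlation, splits of the libraries that mixed the groups also called between 1 and 6 lists. A call at that setting is therefore not by itself particular to the real groups. The list of unfolded protein and integrated stress response genes was lower in CD274_OE. Of the 28 members of this list, 23 were lower and 5 higher, with a median log2 fold change of -0.25, and the list had the smallest p of the 27 (camera adjusted p = 4.71e-10; adjusted p = 0.186 with an estimated correlation, where the call is lost). It was 0.0117 with fry and ranged from 3.29e-15 to 0.186 over the settings and tests run. HSPA5 passed over all genes, and 13 members passed adjusted over the list alone, all 13 lower. Apart from HSPA5 these members were chosen after their values were seen. They include HERPUD1, a factor of the degradation of misfolded proteins (log2 fold change -0.76, SE 0.0798), the lumenal Hsp90 HSP90B1 (-0.65, SE 0.109), the disulfide isomerase PDIA4 (-0.49, SE 0.0608) and the co-chaperones DNAJB9 (-0.65, SE 0.126), DNAJC3 (-0.55, SE 0.0909) and SDF2L1 (-0.65, SE 0.12). MANF, CRELD2 and PDIA6, also proteins of the endoplasmic reticulum, had log2 fold changes of -0.49, -0.38 and -0.23. STC2, CHAC1 and SESN2, which respond to the transcription factor ATF4, had -0.45, -0.61 and -0.27. Going against the rest, ATF4 itself was at 0.13 (SE 0.0805) and the amino acid transporter subunit SLC3A2 at 0.20 (SE 0.0987), neither past the threshold. With 1 library left out, ATF4 ranged from 0.082 to 0.19 and SLC3A2 from 0.11 to 0.29. With GC and length offsets ATF4 was at 0.0455 and SLC3A2 at 0.10. Plasma cells are rich in these chaperones, and immunoglobulin genes summed to 1253 CPM in NC replicate 1, against 2.27 to 31.1 CPM in the other 5 libraries. Without NC replicate 1 the median log2 fold change of the list was -0.26.

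**Figure D2:**
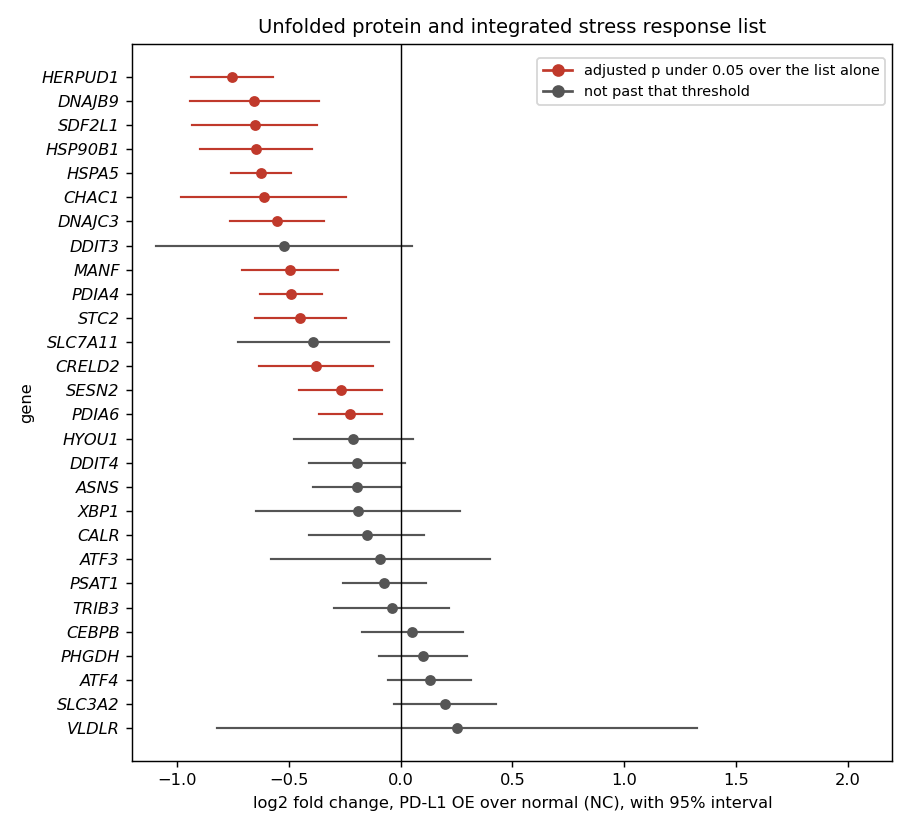
Log2 fold change of CD274_OE over NC for the 28 members of the unfolded protein and integrated stress response list, with 95% intervals (n = 3 libraries per group). Red marks the 13 members past the threshold adjusted over the list alone, all of them left of 0.

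Type I interferon response genes were lower in CD274_OE, with 27 of 32 members below 0 and a median log2 fold change of -0.17 (camera adjusted p = 1.29e-04; adjusted p = 0.771 with an estimated correlation). It was 0.305 with fry and 0.0716 without NC replicates 1 and 2, and ranged from 2.61e-06 to 0.771 over the settings and tests run. With edgeR 0 members passed over all genes and 0 adjusted over the list alone, and 11 had an unadjusted p under 0.05. The antiviral gene IFIT3 had a log2 fold change of -0.31 (SE 0.144), and IFITM3, a restriction factor of viral entry, one of 0.095 (SE 0.109). IFIT3 was at -0.19 without CD274_OE replicate 1, -0.19 without NC replicate 2 and -0.082 without NC replicates 1 and 2. With 1 library left out, IFITM3 ranged from 0.003 to 0.21.

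The lists of NRF2 targets, cytosolic ribosomal proteins and mitochondrially encoded mRNAs were higher in CD274_OE, with median log2 fold changes of 0.11, 0.066 and 0.12. Among NRF2 antioxidant genes 18 of 23 were above 0 (camera adjusted p = 0.00633; adjusted p = 0.771 with an estimated correlation), among ribosomal protein genes 49 of 64 (0.00633; adjusted p = 0.854 with an estimated correlation) and among mitochondrial mRNAs 6 of 6 (0.0167; adjusted p = 0.771 with an estimated correlation). In each list edgeR put 0 members past the threshold, over all genes or adjusted over the list alone, and 6, 3 and 2 members had an unadjusted p under 0.05. Over the settings and tests run, the adjusted p ranged from 2.91e-04 to 0.954, from 2.75e-10 to 0.954 and from 0.00856 to 0.771. The NRF2 targets FTH1, the ferritin heavy chain, and PRDX1, a peroxiredoxin, had log2 fold changes of 0.16 (SE 0.0847) and 0.40 (SE 0.155). RPL8 and RPL4 had 0.26 (SE 0.137) and 0.13 (SE 0.0785), and MT-ND2 and MT-ND4, subunits of respiratory complex I, 0.25 (SE 0.0966) and 0.10 (SE 0.0938). With 1 library left out, these values ranged from 0.095 to 0.24 for FTH1, 0.24 to 0.50 for PRDX1, 0.14 to 0.40 for RPL8, 0.083 to 0.21 for RPL4 and 0.14 to 0.32 for MT-ND2. The ribosomal list lost its call without CD274_OE replicate 1 (adjusted p = 0.599), CD274_OE replicate 2 (0.226) or NC replicate 1 (0.142). The NRF2 list lost it without CD274_OE replicate 1 (0.112, median 0.11), and the mitochondrial list without CD274_OE replicate 3 (0.258, median 0.098) or NC replicate 2 (0.107, median 0.11). The ribosomal median was 0.019 without CD274_OE replicate 1, 0.006 without CD274_OE replicate 2, 0.20 without CD274_OE replicate 3, 0.016 without NC replicate 1 and 0.12 without NC replicate 3, and the NRF2 median 0.065 without NC replicate 2 and 0.19 without NC replicate 3. Without NC replicates 1 and 2 together, the ribosomal, NRF2 and mitochondrial medians were -0.011, 0.007 and 0.072. FTH1 and the ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. The other 7 mitochondrial mRNAs are listed at 0 in all libraries.

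Camera did not call the insulin and eIF3 lists. The mixed form of fry, which allows changes in both directions, called the insulin list (adjusted p = 0.034) and not the eIF3 list (0.464). Of 35 insulin and IGF signalling genes 13 were above and 22 below 0 (camera adjusted p = 0.737), and IRS4 was the 1 member past the threshold adjusted over the list alone. The other insulin receptor substrates, chosen after their values were seen, had log2 fold changes of 0.20 (SE 0.0717) for IRS1 and -0.061 (SE 0.117) for IRS2. IGFBP3, a carrier of IGFs, had -0.069 (SE 0.0805) and the kinase AKT1 0.092 (SE 0.118). With 1 library left out, IRS2 ranged from -0.12 to -5e-04 and IGFBP3 from -0.13 to -0.013. Of 13 eIF3 subunits 8 were above and 5 below 0 (adjusted p = 0.288), with EIF3B at 0.055 (SE 0.0876) and EIF3D at 0.17 (SE 0.065).

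Camera did not call the keratinocyte lists. The mixed form of fry called the wound-activated keratinocyte genes (adjusted p = 0.0101) and none of the other lists in this paragraph (0.12 to 0.925). Basal and hemidesmosome genes had 10 members above and 9 below 0 (camera adjusted p = 0.737), with the basal keratin KRT5 at a log2 fold change of 0.14 (SE 0.0862; 0.072 to 0.18 with 1 library left out) and the caveolar protein CAV1 at 0.055 (SE 0.061). Of 35 epidermal differentiation genes, only 12 had enough counts to be tested. Of these, 7 were above and 5 below 0 (0.923), with KLK5 at 0.13 (SE 0.0683) and DMKN at -0.0072 (SE 0.115). Wound-activated keratinocyte genes had 14 above and 13 below 0 (0.649), with the hyaluronan receptor CD44 at 0.07 (SE 0.0667; 0.027 to 0.11 with 1 library left out). The adjusted p was 0.496 for mesenchymal genes (12 above, 4 below), 0.914 for epithelial junctions (10 above, 14 below), 0.697 for TGF-beta targets (11 above, 8 below) and 0.91 for EGFR ligands and MAPK feedback (11 above, 11 below). Cell cycle genes had 22 above and 16 below 0 (0.496), with MKI67 at -0.071 (SE 0.108; -0.18 to -9e-04 with 1 library left out) and TOP2A at -0.38 (SE 0.213). TOP2A ranged from -0.60 without CD274_OE replicate 3 to -0.23 without NC replicate 1, and was at -0.0021 without NC replicates 1 and 2.

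Among the other lists, immune checkpoint ligands besides CD274 showed 5 members above and 11 below 0, with the poliovirus receptor PVR at a log2 fold change of 0.11 (SE 0.102) and CD47 at -0.041 (SE 0.0642), both chosen after their values were seen. With 1 library left out, PVR ranged from 0.034 to 0.19 and CD47 from -0.058 to -0.0042. With CD274 included the adjusted p was 0.935 with camera and 0.0199 with fry, and the median of -0.038 lies against the mean of 0.21. The NF-kB and cytokine list had 9 above and 15 below 0 (0.117). It was called lower without CD274_OE replicate 2 (adjusted p = 0.0384), without NC replicate 1 (0.00782) and with GC and length offsets (0.0283). For 1 direction, its adjusted p ranged from 0.00782 to 0.771 over the settings and tests run. The mixed form of fry called it (adjusted p = 4.26e-04). TNFAIP2 of the NF-kB list had a log2 fold change of 0.48 (SE 0.103), STARD4 of the cholesterol list -0.68 (SE 0.137) and MFAP5 of the fibroblast list -0.62 (SE 0.179). Each passed adjusted over its list alone, not over all genes, and STARD4 and MFAP5 were chosen after their values were seen. The adjusted p was 0.0556 for glycolysis and hypoxia, 0.112 for immediate early genes, 0.91 for interferon-gamma and antigen presentation, 0.91 for cholesterol and fatty acid synthesis and 0.914 for heat shock. Immediate early genes were called lower without CD274_OE replicate 2 (0.0457), NC replicate 1 (0.0306) or NC replicate 3 (0.023) and with GC and length offsets (0.00797; range 0.00797 to 0.971). Glycolysis and hypoxia genes were called higher without CD274_OE replicate 1 (0.0259) or NC replicate 3 (0.0431; range 0.0259 to 0.954). Median, mean and test also differed in sign, near 0, for epidermal differentiation, EGFR ligands, mesenchymal genes, junctions, cell cycle, cholesterol and heat shock.

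Marker lists of other cell types were not called either, with camera adjusted p of 0.496 for fibroblasts, 0.492 for melanocytes, 0.496 for leukocytes, 0.935 for endothelium and 0.391 for a kidney line. Low counts left few members to test: 4 of 14 for fibroblasts, 2 of 9 for melanocytes, 2 of 15 for leukocytes, 3 of 10 for endothelium and 6 of 12 for the kidney line. These tests therefore cannot show that a cell type is absent. The kidney-line list was called lower without NC replicate 1 (adjusted p = 0.0306, 6 members, median log2 fold change -0.15), and its adjusted p ranged from 0.0306 to 0.934 over the settings and tests run. Leukocyte markers summed to between 14.1 and 18.9 CPM in all 6 libraries. Most of this sum was CD68, with 241 to 288 counts per library of list totals of 266 to 349. The even sum therefore says little about leukocyte RNA. Counts of the leukocyte gene PTPRC were 16, 1 and 2 in CD274_OE and 5, 21 and 4 in NC. Immunoglobulin genes, which are on none of these lists, summed to 69, 308 and 44 counts in CD274_OE and to 24097, 574 and 44 in NC.

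**Figure D3:**
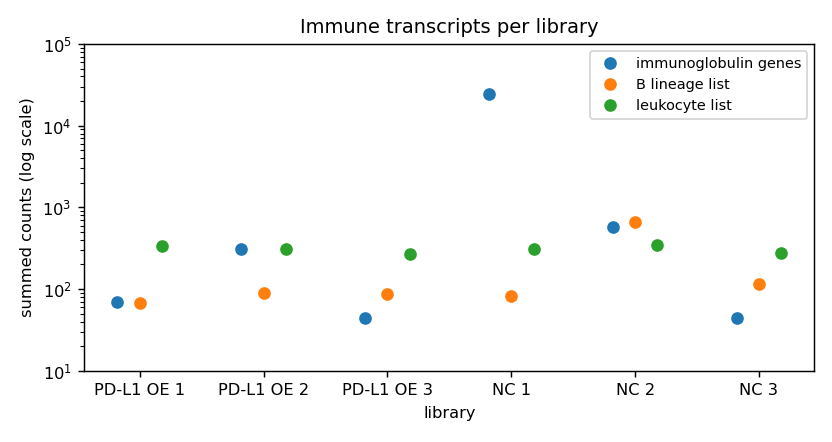
Summed counts per library, on a log scale, of immunoglobulin genes, 13 B-lineage genes and the leukocyte marker list. NC replicate 1 holds 24097 immunoglobulin counts and NC replicate 2 holds 668 B-lineage counts, against 67 to 116 B-lineage counts in the other 5 libraries.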

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

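The fits with GC and length offsets and without NC replicates 1 and 2 were chosen after the data were seen; the rest were planned. CD274 kept its direction and its call in all 15 alternatives (log2 fold change 4.56 to 4.76). The main count of 2 genes became 22 with DESeq2 (5 higher, 17 lower), 11 with no filter (1 higher, 10 lower), 11 with GC and length offsets (3 higher, 8 lower), 6 without NC replicates 1 and 2 (6 higher, 0 lower) and 1 with the replicate number as a block (1 higher, 0 lower). Leaving out 1 library at a time gave 3 to 5 genes, 1 to 3 higher and 0 to 3 lower, and only CD274 passed in more than 1 of these fits. Same-numbered libraries had correlations of -0.104, -0.0775 and -0.181 after group means were removed, which gives no sign of pairing by number. The labels are silent on pairing, and these few correlations cannot exclude it. Under the block HSPA5 had an edgeR adjusted p of 0.848. IRS4 passed with DESeq2 (log2 fold change -3.60) and no filter (-3.53), and stayed between -4.02 and -3.09 with 1 library left out. EIF3I was at -0.001 without NC replicates 1 and 2. With an estimated correlation the adjusted p was 0.186 for the stress list, 0.771 for interferon, 0.771 for NRF2, 0.854 for ribosomal proteins and 0.771 for mitochondrial mRNAs; with fry, the last 4 were 0.305, 0.495, 0.786 and 0.377, and without NC replicates 1 and 2 they were 0.0716, 0.954, 0.954 and 0.607. With 1 library left out, adjusted p was 2.91e-04 to 0.112 for NRF2, 2.75e-10 to 0.599 for ribosomal proteins, 0.0134 to 0.258 for mitochondrial mRNAs and at most 8.96e-06 for the stress list. Log2 fold changes near 0 changed sign: CD47 was at 0.12 with GC and length offsets, EIF3B at -0.019 there and -0.0401 without NC replicates 1 and 2, and AKT1 at -0.056, IFITM3 at -0.084 and MKI67 at 0.058 in that last fit. DMKN was at 0.0021 with limma-voom, 0.0023 with no filter and 6e-04 with the block. With 1 library left out, AKT1 ranged from -0.039 to 0.18, EIF3B from -0.0086 to 0.13, DMKN from -0.11 to 0.11 and MT-ND4 from -0.0044 to 0.16. The cause of these shifts was not tested, and leaving out libraries also leaves fewer samples. Fewer samples alone do not account for the unadjusted count of 1108 genes. It rose to 2377 without CD274_OE replicate 3 and to 1738 without NC replicate 3, and fell without each of the other libraries. On the first principal component these 2 libraries lie on the other side from the rest of their group. Of the lists not called, 5 were called for 1 direction in some setting: NF-kB, immediate early, glycolysis, kidney-line and, with fry, checkpoint ligands, which include CD274. In the main fit, the mixed form of fry also called the insulin and wound-activated keratinocyte lists. At this depth the counts of IRS4, 1 to 57 per library, limit its precision.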

Other observations

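The tests of a GC or length trend, of the splits behind the gene count and of the further endoplasmic reticulum genes were set before their results were seen; all other tests here were chosen after the result was seen.

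Further genes of folding and quality control in the endoplasmic reticulum, outside the fixed list, were also lower in CD274_OE. Of 26 such genes 21 were below 0 and 5 above, with a median log2 fold change of -0.15 and a camera p of 1.41e-04 (0.0131 with an estimated correlation), and with edgeR 0 passed adjusted over the list alone and 8 had an unadjusted p under 0.05. SEL1L, a part of the degradation machinery, was at -0.36 (SE 0.11) and the lectin chaperone CANX at -0.18 (SE 0.0617), while EDEM2 was at 0.13 (SE 0.0777) and the translocon subunit SEC61A1 at 0.095 (SE 0.0748). With 1 library left out, SEL1L ranged from -0.45 to -0.26, CANX from -0.20 to -0.15, EDEM2 from 0.10 to 0.17 and SEC61A1 from 0.064 to 0.15. These further genes were measured in the same libraries as the fixed list, and the splits were not run for them. Their lower levels are therefore not independent of the result for the fixed list. The fixed stress list was also divided by function after its members' values were seen. All 13 chaperone and folding members were below 0 (median -0.50, camera p = 4.26e-15, or 0.00114 with an estimated correlation), and 10 of 15 members tied to ATF4 were (median -0.12, camera p = 0.0143, or 0.133 with an estimated correlation), with 3 of these, STC2, CHAC1 and SESN2, past the threshold adjusted over the list alone. The gap between the mean log2 CPM of the parts was 1.94 ± 0.0399 in CD274_OE and 2.26 ± 0.014 in NC (SD, n = 3), a difference of -0.32 without overlap (exact permutation p = 0.1, the smallest possible). Since the division followed from the values, this gap restates them and does not decide whether the parts respond differently.

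The lower stress list was weighed against technical explanations. Offsets for GC content and transcript length left the list's median log2 fold change at -0.27, which argues against such a trend as the whole cause. Without NC replicate 1, the library rich in immunoglobulin, the median was -0.26, which argues against plasma cell RNA there. Of the 10 splits of the 6 libraries, 1, the real one, gave a list p as small, and 10 splits are too few for a share under 0.05. The -log10 p of this list was 10.8 in the real split against at most 4.09 in the others. This list had the smallest p of the fixed lists in the real split, so following it alone favours that split. The smallest p of any list was not taken in the other splits, so this contrast decides nothing about the grouping. Since NC is labelled as normal cells, the vector, selection and culture of the CD274_OE cells cannot be separated from PD-L1 and stay open.

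The lower IRS4 count was weighed in the same way. The summed counts of IRS4 and ENSG00000261409, 17 in CD274_OE and 236 in NC, differed by -3.77 on the log2 scale. Both genes had been seen to be lower in CD274_OE when this sum was chosen, so it restates their counts and is no separate test. Lower counts in both genes are not what a move of reads from one to the other would give. The upper limit of the exact ratio, 0.161, argues against counting error alone. NC replicate 3, with few immune transcripts, had 0.605 times the mean IRS4 CPM of NC replicates 1 and 2, which argues against immune cells as the source of the IRS4 counts in NC. A difference tied to PD-L1, and one between cell stocks handled apart, both remain open.

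Immunoglobulin and B-lineage transcripts stood out in NC replicates 1 and 2. CD274_OE replicate 2 also held more immunoglobulin (14.8 CPM) than CD274_OE replicates 1 and 3 (3.35 and 2.78 CPM), against 31.1 CPM in NC replicate 2. The immunoglobulin CPM of NC replicate 1 was 553 times that of NC replicate 3, which argues against a state shared by the normal HaCaT group. All 9 genes of the plasma cell list were higher in NC replicate 1 than in every library other than NC replicate 2. JCHAIN (1517 counts) and MZB1 (90 counts) had been seen when the list was written, and all 7 others, which had not, met the same bound. The bound sets no fold size. Of these 7, DERL3 (76 counts against at most 3), TNFRSF17 (17 against 0) and IRF4 (10 against at most 4) stood apart. FCRL5 had only 5 counts, and SLAMF7 had 217 against 126 to 179 in the other libraries. CD38 had 32 and POU2AF1 had 19, against 39 and 16 in NC replicate 2. NC replicate 2 had 89 counts of CD79A and 121 of CD79B, against at most 8 and 11 in the other libraries. A candidate explanation is RNA or reads from immune cells outside the culture, such as carry-over from other libraries; immunoglobulin counts were 0.125% of NC replicate 1, and no biological explanation other than a state shared by the group was tested. Of the 13 B-lineage genes 2 had enough counts to be tested, with a camera p of 0.252.

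The number of genes past the threshold did not set the real groups apart. Of the 10 splits, 4 gave as many genes as the real 2, the real one included, and the highest other split gave 604. That split sets CD274_OE replicates 1 and 2 with NC replicate 3 against CD274_OE replicate 3 with NC replicates 1 and 2, the same sides as the first principal component (32.5% of variance), and points to a structure of the samples other than the groups; it gave 3126 genes at an unadjusted p under 0.05 against the real 1108. Of the 10 splits, 2 called as many of the 27 lists with the preset correlation as the real 5, the real one included, and the highest other called 6 (CD274_OE replicates 1 and 3 with NC replicate 1 against the rest). Every other split called at least 1 list, so calls at the preset correlation also arise when the groups are mixed. The estimated correlation was 0.58 for ribosomal proteins, 0.33 for mitochondrial mRNAs and 0.26 for NRF2 targets, against the preset 0.01. It was 0.25 for the interferon list and 0.044 for the stress list. These 10 splits are too few for a share under 0.05.

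Read-through genes, which join neighbouring genes, more often had 0 counts in a library while reaching at least 50 in another, 7 of 48 (14.6%) against 46 of 12157 other genes (0.378%; Fisher's exact p = 1.24e-09, across genes, which are not independent replicates). SENP3-EIF4A1 had 0, 1541 and 1678 counts in CD274_OE and 0, 0 and 726 in NC.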
